A study of Ecsenius pulcher with 24 samples.

How the data were processed

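Skeletal muscle from the front of the tail of 24 individuals of *Ecsenius pulcher*, a small coral reef blenny, was profiled by sequencing of polyadenylated RNA. Per the labels, each replicate was a separate fish, and the 24 fish formed 4 groups of 6. Hypoxic fish and time-matched control fish were sampled either during the low-oxygen exposure (the acute time point) or after reoxygenation and recovery (the post time point). Groups and replicate numbers were taken from the sample titles.

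The deposited table held estimated counts for 518956 features in 24 columns, per the file headers, with no scaling between libraries. The feature IDs have the form that the Trinity assembler gives to assembly genes, that is, clusters of transcripts assembled from the reads, nested in larger components. The submitters' processing notes name Trimmomatic, RSEM and kallisto; their versions, the assembly settings and any annotation are not given in the sources used here. The files do not pair the IDs with gene names, so features are given by ID and no gene is named. For the same reason the 28 gene lists fixed before the data were examined could not be tested. In post hypoxic replicate 4 every value was whole, whereas 3.39% to 7.33% of the nonzero values of each other library were not; the reason is not given in the sources used here. Estimated counts were rounded to whole numbers before any test.

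Library totals lay between 31085706 and 43603403 counts. Features with too few counts were removed with the filterByExpr function of edgeR (minimum count 10, minimum total count 15), which left 65664 features, or 12.7% of the table, and 98.9% to 99.6% of the counts of each library. Libraries were scaled by trimmed mean of M-values (TMM) factors. The quasi-likelihood test of edgeR (version 4.0.16) was fitted to all 24 libraries with 4 group means, and p-values were adjusted by the Benjamini-Hochberg method over all features tested, with a threshold of 0.05. Contrasts were acute hypoxic minus acute control, post hypoxic minus post control, the difference of those effects, and post control minus acute control. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Expression levels are CPM (counts scaled to library size) of TMM-scaled libraries.

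Library measures and set scores were compared by exact two-sided permutation tests of the difference of means over the 924 ways to divide 12 libraries into groups of 6. Differences between effects were tested with 100000 random relabellings within time points. The score of a set was the mean log2 CPM of its features, with a prior count of 2 and each component counted once. Principal components were computed from log2 CPM of the 2000 most variable features tested. No pair of libraries within a group had counts that agree within sampling noise: over 60 pairs the chi-square per feature was 29.6 to 348, against 1 for sampling noise alone. The sources used here name no molecular identifiers, so counts are not known to be independent molecules.

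The features named were fixed by a rule before the data were examined: per contrast, the 2 higher and the 2 lower features with the smallest p among those past the adjusted threshold. The test was tested on simulated data with the means, library sizes and spread of the 65664 features. For the acute comparison 50 features were changed at each fold, all in the same simulated data and equally in every hypoxic fish. The test recovered 14% of features changed 2-fold, 64% of those changed 4-fold, 92% at 8-fold and 84% at 16-fold. It made 4 calls among unchanged features. Each feature was drawn independently, so variation shared by many features of a fish was absent. These rates need not hold for the real data. With fewer changed features the adjusted threshold is harder to pass, so recovery would tend to be lower.

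Alternatives listed before the data were examined were DESeq2 (version 1.42.0), DESeq2 size factors, upper-quartile factors, no count filter, a stricter filter (1 CPM in 6 libraries), limma voom with quality weights (limma version 3.58.1), a replicate block, other thresholds, only the libraries compared, and each library left out in turn. Sums per component, sums of matching pairs, a robust spread, the newer quasi-likelihood method of edgeR, removal of the 100 most abundant features, and the score tests on the acute features were chosen after seeing the data. Sums over isoforms were not run, because the IDs were already at the level of assembly genes.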

Results

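Muscle transcript levels were measured in 24 reef blennies, with 6 fish in each of 4 groups: acute control, acute hypoxic, post control and post hypoxic. Oxygen in the exposures followed profiles recorded on nearby reefs. Library totals were 31085706 to 43603403 estimated counts, and 106273 to 158099 features had at least 1 count in a library. The 10 most abundant features took 9.58% to 30.9% of the counts of a library.

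The acute comparison asked which transcripts differed while oxygen was low. During hypoxia 14 features were higher than in time-matched controls and 0 were lower, out of 65664 tested with edgeR (adjusted p 0.0309 to 0.0487, n = 6 fish per group). Their fold changes ran from 2.91 to 23.8, with a median log2 fold change of 3.32 and standard errors of 0.26 to 0.84, and the 14 features belonged to 12 assembly components. TRINITY_DN10369_c0_g1 averaged 0.261 ± 0.139 CPM (SD, n = 6) in controls and 4.47 ± 3.37 CPM in hypoxic fish, a log2 fold change of 4.08 (SE 0.65, edgeR adjusted p 0.0309). TRINITY_DN16783_c1_g1 averaged 0.358 ± 0.226 CPM (SD, n = 6) in controls and 8.11 ± 6.84 CPM in hypoxic fish, a log2 fold change of 4.52 (SE 0.72, edgeR adjusted p 0.0309).

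For all 14 of these features, hypoxic replicates 2 to 6 each lay above every acute control fish. Acute hypoxic replicate 1 lay above every control for 3 of the 14. The mean score of the 14 features was -0.02 ± 0.51 log2 CPM (SD, n = 6) in acute controls and 2.90 ± 1.31 in acute hypoxic fish, a difference of 2.92 (SE 0.58) or 7.55-fold, on features selected for this contrast. In replicate 1 the score stood 0.47 log2 units above the control mean, within the control range, which reached 0.53; in replicates 2 to 6 it stood 2.79 to 4.31 units above. At an unadjusted p of 0.05, 1454 features were higher and 913 lower, together 3.60% of those tested, less than the 1 in 20 expected with no effect. This share depended on the fit. DESeq2 gave 2905 of 65664, also under 1 in 20. The share was above 1 in 20 with voom (6294 of 65664) and in the 12 acute libraries alone (3881 of 57675). It was also above 1 in 20 without acute hypoxic replicate 1 (3765 of 65664). The count of 14 was 0 when the model was fitted to the 12 acute libraries alone, and 0 in 9 of the 24 refits that left out a library: each of the 6 acute controls, and acute hypoxic replicates 4, 5 and 6. It was 48 without acute hypoxic replicate 1, 24 without post hypoxic replicate 1, 9 without acute or post hypoxic replicate 2, and 6 or 7 without acute hypoxic replicate 3, post control replicates 1, 2, 4 and 5, or post hypoxic replicates 3, 4 and 5. DESeq2 called 67 features (59 higher, 8 lower) and limma voom 116 (104 higher, 12 lower), with all 14 among the higher ones in both.

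**Figure D1:**
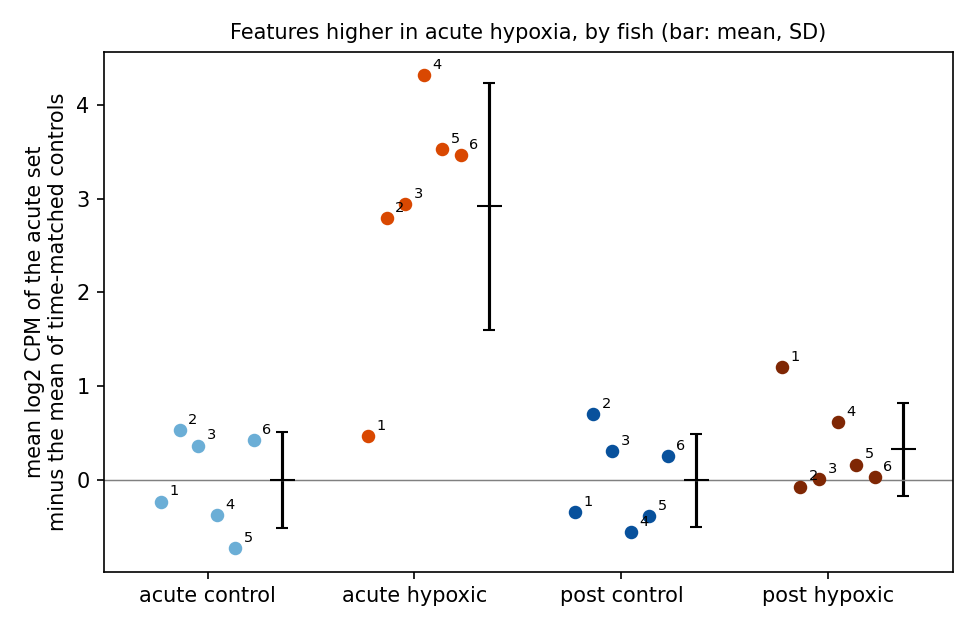
Mean log2 CPM of the 14 features higher in acute hypoxia, minus the mean of the time-matched controls, for each fish (points, numbered by replicate), with the mean and SD of each group. Acute hypoxic replicate 1 stood at 0.47, and replicates 2 to 6 at 2.79 to 4.31; the features were selected on the acute contrast.

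**Figure D2:**
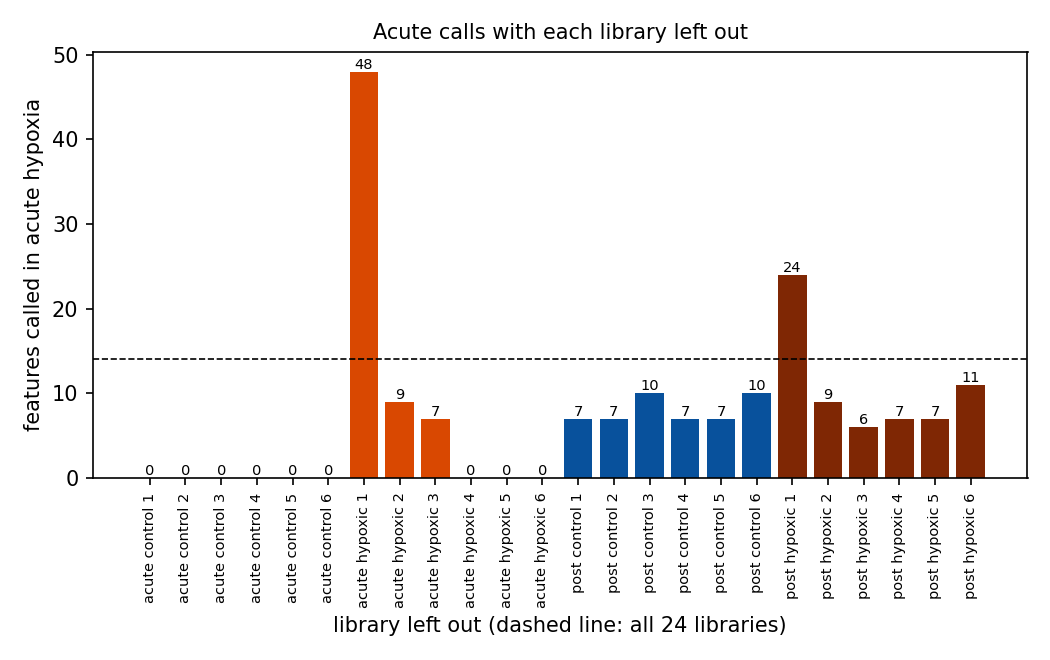
Number of features called in acute hypoxia when each library was left out, with bars coloured by group and a dashed line at the 14 calls of all 24 libraries. The count was 0 in 9 refits and 48 without acute hypoxic replicate 1.

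After reoxygenation and recovery, the question was which transcripts still differed from time-matched controls. No feature passed the threshold with edgeR (0 calls, smallest adjusted p 0.187). An unadjusted p under 0.05 was found for 2519 features (921 higher, 1598 lower). That is 3.84% of those tested, less than the 1 in 20 expected with no effect. With voom the number was 2144 of 65664. Without post hypoxic replicate 3 it was 3735 of 65664, above 1 in 20. DESeq2 called 7 features and limma voom 0. Of the 14 features higher during hypoxia, 8 had a higher mean after recovery, and 0 passed when adjusted over the 14 alone (lowest adjusted p 0.0868 with edgeR). TRINITY_DN10369_c0_g1 averaged 0.106 ± 0.099 CPM (SD, n = 6) in post controls and 0.356 ± 0.105 in post hypoxic fish, a log2 difference of 1.86 (SE 0.69) that did not pass. TRINITY_DN16783_c1_g1 had a log2 difference of 0.73 (SE 0.65), which did not pass either. For TRINITY_DN10369_c0_g1 the lowest post hypoxic fish (0.254 CPM) lay above the highest post control (0.246 CPM). Its unadjusted edgeR p was 0.0124, on 20 counts in post controls and 81 in post hypoxic fish. The score of the 14 features differed by 0.33 log2 units (95% interval -0.31 to 0.99; exact permutation p 0.275, n = 6), so a residual difference up to the upper bound was not excluded. It was 0.15 without post hypoxic replicate 1, 0.22 without post control replicate 4, and 0.08 to 0.12 on 4 other sets of acute features chosen after seeing the data.

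The change of the hypoxia effect between time points was tested directly. No feature passed for the difference of the effects with edgeR (0 calls, smallest adjusted p 0.889), against 14 calls with DESeq2 and 0 with limma voom. An unadjusted edgeR p under 0.05 was found for 2297 features, or 3.50%, also less than 1 in 20. With voom the number was 4419 of 65664, above 1 in 20. The score of the 14 features rose by 2.59 log2 units more during hypoxia than after recovery (permutation p 0.0122). All 14 had an edgeR p for the difference of 0.0291 or less when adjusted over the 14 alone, but the set was selected on its acute effect, which biases both results upward. Across the 65664 features, the acute and post log2 fold changes correlated with Pearson r 0.0635 and Spearman rho 0.0703, and 52.2% had the same sign. Relabelling fish within time points gave r from -0.200 to 0.212, with 25 of 60 relabellings at least as far from 0. Features are not independent replicates, and the 2 contrasts share no library.

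The control fish of both time points were compared to show how the sampling series differed without hypoxia. In post controls 2679 features were higher and 2498 lower than in acute controls (5177 in all, edgeR), and 658 of these changed by at least 3 log2 units. TRINITY_DN10735_c0_g1 averaged 1.05 ± 0.171 CPM (SD, n = 6) in acute controls and 159.7 ± 50.01 in post controls (log2 fold change 7.24, SE 0.28). TRINITY_DN5268_c2_g1 went from 0.693 ± 0.226 to 59.9 ± 18.3 CPM (log2 fold change 6.42, SE 0.28). TRINITY_DN425_c0_g1 went from 17.9 ± 0.877 to 0.736 ± 0.306 CPM (log2 fold change -4.58, SE 0.31). TRINITY_DN603_c2_g1 went from 17.2 ± 6.04 CPM to 7 counts over the 6 post control libraries (fitted log2 fold change -8.98, SE 0.60), and without post control replicate 5 the fitted value was -10.91.

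Hypoxic fish showed much of the same difference in libraries not shared with that contrast. Between acute and post hypoxic fish 3981 features passed (1718 higher, 2263 lower, edgeR), and 2123 passed in both contrasts in the same direction. Of those, 1045 were higher and 1078 lower, against 70.09 and 86.09 for independent lists. Of the 5177 features called in controls, 97.9% had the same sign in hypoxic fish. Library names also differed in style between the time points, so sampling time and any sampling or library batch were the same division of the libraries and cannot be told apart.

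Time point explained 35.2% of the variance of the 2000 most variable features among controls (exact permutation p 0.00216, n = 6 per group, the smallest that 924 permutations give). The division into hypoxic and control fish took 10.4% at the acute point (exact permutation p 0.236, n = 6). At the post point it took 7.56% (exact permutation p 0.827, n = 6). Random divisions of the same fish often took as much, so neither share shows a contribution of hypoxia. The 2000 features were chosen for their variance over all 24 libraries, which include both time points. The first principal component held 32.8% of the variance and separated the time points, with means of -51.44 ± 22.95 in acute controls and 50.6 ± 10.7 in post controls (SD, n = 6). On the component holding 4.95%, acute hypoxic fish averaged 15.5 ± 12.8 and acute controls -11.0 ± 14.2 (exact permutation p 0.00866, adjusted p 0.156 over 18 comparisons, n = 6), so none of the 18 passed. The 10 most abundant features took 23.3% ± 5.84 of counts in acute controls and 13.1% ± 2.99 in post controls (exact permutation p 0.00649, n = 6). Distance of fish from their group centroid differed between hypoxic and control fish by 1.77 at the acute point (exact permutation p 0.818, n = 6). It was -3.34 without acute hypoxic replicate 1. At the post point the difference was -5.13 (exact permutation p 0.264, n = 6), and -7.22 to -2.37 leaving out libraries (-2.37 without post control replicate 3). A second measure was 1 minus the mean Spearman correlation of a fish with the other fish of its group. Its post difference was -0.0242 (exact permutation p 0.0584). Each correlation enters the values of 2 fish, so they are not independent and this p is only approximate. For distance from the centroid over all tested features the post difference was -20.9 (exact permutation p 0.331).

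**Figure D3:**
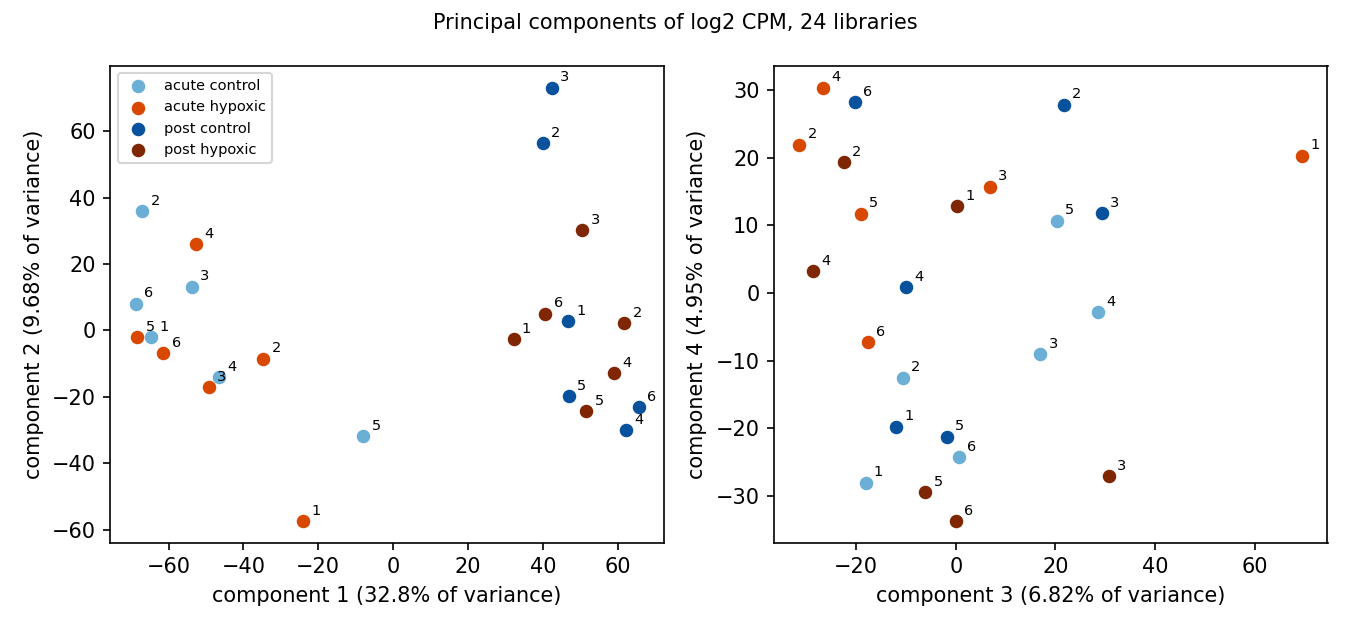
Scores of the 24 libraries on the first 4 principal components of log2 CPM of the 2000 most variable features, coloured by group and numbered by replicate; axes give the share of variance. The first component (32.8%) separates the time points, and acute control replicate 5 (-7.96) lies nearest to 0 of the acute fish.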

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

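Tests on read number, on RNA of other cells, on the batch and on the matching pairs were chosen after the result was seen, as were the score of the 14 acute features and the margin that decides the test of other cells. Leave-one-out, DESeq2 and voom values had been seen before any of the explanations was written down. Of 64 group values examined, 5 held a fish far from the rest of its group, and chance gives about 1 in 20.

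Acute hypoxic replicate 1 lay 97.0 units from its group centroid, against 61.4 to 73.7 for the other hypoxic fish, and its score on the 14 acute features was within the control range. Too few reads would not give this: its count over the set was 0.1 of that expected (1464 against 14599) in a library 0.887 times the mean size of the others. On the 48 features called without this library it stood 0.262 log2 units above the control mean, under the highest control at 0.573, which is consistent with a wrong label or a fish that was not exposed; a fish that responded less predicts the same and was not tested. On other sets it stood 0.81 above the control mean on the DESeq2 set (highest control 0.31). On the voom set it stood at 0.32 (highest control 0.24), and on the set at an adjusted p of 0.1 at 0.54 (highest control 0.57). All these sets were chosen with it included, and no acute control stood out as a swap partner. On principal component 4 this library scored 20.3, above every acute control (highest 10.7), with the other acute hypoxic fish at -7.22 to 30.4. It therefore did not lie with the controls on every measure. The group difference on that component did not pass over the 18 comparisons (exact permutation adjusted p 0.156). RNA of other cells stays open: the 100 most abundant features of the other hypoxic fish had a median log2 ratio of -1.3 in this library relative to them, against -2.87 for the set, with interquartile ranges of 2.59 and 2.62 too wide to decide.

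Of 61 splits of the acute fish, the real one included, only the real one gave as many as 14 acute calls. The highest other gave 4. The other splits were a random draw, not all that exist, and the post fish were relabelled in the same fits. Other splits of the post fish gave up to 106 post calls. The real post split gave 0, which every split reaches, so this comparison says nothing about chance. For the time point difference 1 of 41 splits, the real one, gave as many, with 5177 calls against 1 for the highest other. Without the 100 most abundant features 5032 of the calls remained, so the calls did not rest on these features being present. Both fits were scaled by TMM factors, which already limit the weight of such features, so their effect without scaling was not tested. A sampling or library batch may account for any part of the time point difference. As 0 libraries of either naming style occur at the other time point, batch and time cannot be told apart. A change with time or recovery conditions was not tested separately.

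The effect of hypoxia on the acute set differed between time points by 2.59 log2 units, on features selected at the acute point. Acute control replicate 5 had a first component score of -7.96, against -68.8 to -46.6 in the other acute controls. TRINITY_DN16783_c1_g1 was at 0.808 CPM in acute control replicate 2, against 0.20 to 0.32 CPM in the other acute controls. TRINITY_DN603_c2_g1 was at 0.142 CPM in post control replicate 5 and 0.0732 CPM in post hypoxic replicate 2, above the other fish of each group, on 7 and 4 counts per group.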

How the results depend on the processing

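Sums per component, sums of even pairs, the robust and the newer quasi-likelihood fits and the removal of the 100 most abundant features were chosen after seeing the data; sums over isoforms and the tests of the 28 gene lists were not run. The acute count of 14 became 67 with DESeq2, 8 with DESeq2 size factors, 7 with upper-quartile factors, 967 with no filter, 6 with the stricter filter, 116 with voom, 34 at an adjusted p of 0.1, 0 in the fit of 12 libraries, 6 with even pairs summed, 7 with a robust spread, 30 with the newer method, 7 without the 100 most abundant features and 0 to 48 leaving out libraries. Summed per component it was 12, of which 10 were components of the set. With a replicate block it was 0, but not all same-numbered fish correlated over 0.1, so the numbers were not taken to pair them: 1 of 6 pairs did at the acute point (-0.264 to 0.134) and 3 of 6 at the post point (-0.158 to 0.433), with 1 and 2 of them correlating best with their own number. Each of the 14 stayed higher in every 4-group fit that tested it as a feature. TRINITY_DN10369_c0_g1 ranged from 3.66 to 4.39 and TRINITY_DN16783_c1_g1 from 4.01 to 4.90. The post count of 0 became 7 with DESeq2, 1263 with no filter, 2 with the newer method, and 0 to 1 leaving out libraries (1 without post hypoxic replicate 4). The difference of effects went from 0 to 14 with DESeq2, 915 with no filter, and 0 to 3 leaving out libraries (3 without acute hypoxic replicate 1). The control time count of 5177 became 8044 with DESeq2, 8281 with no filter and 8592 at an adjusted p of 0.1, and 3485 to 6115 leaving out libraries; the replicate block gave 4028. Features called both in acute and post went from 0 to 121 with no filter. Of the calls with no filter, 664 of 967, 556 of 1263, 467 of 915 and 5894 of 8281 passed the count filter. Effect correlation ranged from -0.0455 (without post control replicate 3) to 0.134. Leaving out libraries turned differences near 0: total counts post -407329 to 1149410, features detected post -566 to 8536, top 10 share post -0.333 to 1.11, TMM factor post -0.0929 to 0.0327, component 1 acute -1.84 to 11.7 and post -3.83 to 2.09, component 2 post -18.3 to 2.34, component 3 post -12.6 to 0.0741, and spread acute -3.34 (without acute hypoxic replicate 1) to 4.13. Component 3 acute kept its direction, from -23.9 to -3.69, and passed an unadjusted exact p of 0.05 at -23.9, without acute hypoxic replicate 1 (exact permutation p 0.0498). With all tested features, component 1 acute was -2.79, component 3 acute 2.01 and post 13.1. Component 4 acute, 26.5 in the main setting, was -19.7 (exact permutation p 0.357). Each of these axes was turned to correlate positively with its main counterpart. They come from a separate decomposition and need not match the main ones, so a change of sign is hard to interpret. The post difference of 0.33 in the score of the 14 was 0.15 (without post hypoxic replicate 1) to 0.47 leaving out libraries; on sets chosen after seeing the data by DESeq2, by voom, without acute hypoxic replicate 1 and at an adjusted p of 0.1 it was 0.10, 0.09, 0.08 and 0.12 (exact permutation p 0.613 to 0.738). The cause of these changes was not tested. At this depth and with 6 fish per group, 14% of 2-fold changes were recovered in the simulated acute comparison, which changed 50 features at each fold together. Each feature was drawn independently there.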

Other observations

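The test of the matching pairs was chosen after the pattern was seen, and the test of shared variation was not. Among 18425 features with a mean of at least 200 counts, 5459 pairs kept a steady ratio over all libraries (log2 SD at most 0.25), and 4018 of the pairs were at equal levels within 0.2 log2 units. That is 73.6% of the pairs, against a mean of 9.80% and at most 11.2% for random pairings of the same features, which may reflect reads split evenly between near-identical assembly genes, such as alleles or recent copies; no sequences were used here to look. Of these even pairs, 2825 joined different components, and they held 62 of the 100 most abundant features and 55.7% of counts. The 2 most abundant features formed such a pair, at 5.23% and 5.27% of counts in acute controls and 1.52% and 1.48% in post controls. On simulated even splits of 100 features among shuffled features, the search found 94 of the 100 pairs and also 122 other pairs. Of the even pairs called between control time points, both members were called in 415 and only 1 member in 113, so a count of features may overstate the number of genes.

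The 14 acute features also varied together in fish that saw no hypoxia. Over the 12 control fish, after removal of time point means, the mean pairwise correlation of the 12 components was 0.319, against a median of -0.00326 and a 95th percentile of 0.106 in 10000 random sets of similar level (percentile 99.94). The 14 features were selected on a contrast that used 6 of these 12 fish, and the random sets were matched on level only. The percentile is therefore not independent of that selection. A candidate explanation is a shared programme that was active to differing degrees in control fish. Reads split between near-identical assembly genes of different components could also raise this correlation, which was not tested. TRINITY_DN16783_c1_g1 and TRINITY_DN17519_c0_g1 averaged 8.11 and 8.25 CPM in acute hypoxic fish, and 0.358 and 0.464 CPM in acute controls. Only 6 of the 14 had enough counts for the pair search, and 2 of those were in an even pair.

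Other splits of the post fish gave up to 106 calls where the real split gave 0. The split with 106 placed post control replicates 1, 4 and 6 with post hypoxic replicates 2, 3 and 4, and 8 of 60 relabellings gave any call. This may point to a structure among the post fish that does not follow exposure, but the number of calls without such a structure was not tested. For the difference of effects the real split gave 0 calls and the highest other gave 7. With a real count of 0, all 61 of 61 splits gave at least as many in both cases by construction, so these counts of splits say nothing about chance. Post control replicate 5 held 33 features of at least 50 counts with at most 1 count elsewhere (9495 counts), against 0 to 8 in the other libraries.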
